A study of Mus musculus with 8 samples.

How the data were processed

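RNA from the colon of adult mice was measured on 8 Affymetrix expression arrays, which carry short DNA probes grouped into probe sets, each reading the transcript of a gene. The labels give 3 arrays titled WT and 3 titled STAT5b-/-, the latter from mice deficient in the transcription factor STAT5b. A further 2 arrays are titled REF and have the wild type genotype; the labels do not say what REF stands for. Per the labels' protocols, total RNA was extracted on silica columns, and 100 ng per sample was amplified once and labelled with biotin. The array type is not given in the sources used here. Nothing in the labels says whether the replicates are separate animals, so p-values measure only the spread between these samples, which may be technical.

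The deposited value table holds 26180 probe sets, and its unit is a ratio. RMA, which corrects background, normalizes arrays to one distribution and summarises probes, is named in the submitters' processing notes, without a version. The values as deposited are linear and not log2: in every probe set the mean of the 3 WT arrays is 1, to within 1.87e-07, so the authors' values are ratios to the WT mean. The lowest value is exactly 0.01, which was treated as a floor and reached in at least 1 array by 19 probe sets. Dividing each probe set by its own WT mean does not alter log2 differences within a gene. It does remove the level of one probe set against another, so no gene could be called bright or dim, and no filter on dim probe sets was possible. The REF replicate 1 and REF replicate 2 columns differed by at most 2.47e-07 of their value, less than any sampling noise, and were counted as 1 sample, REF. The number of arrays limits the precision; no scanner intensities or detection calls were used here. Control probe sets for RNA quality were not analysed here.

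Probe set identifiers contain RefSeq transcript accessions, which were matched without version to the RefSeq gene table of assembly GRCm38.p6, used for names and for gene order only. Of the 26180 probe sets, 15228 matched 1 symbol, 0 matched several and 10952 matched none. The matched probe sets gave 14351 genes, of which 661 had more than 1 probe set.

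Ratios were transformed to log2 with no pseudocount, and the probe sets of a gene were averaged. The test as planned before the data were examined assumed log2 RMA values and took the probe set with the highest mean for each gene. On ratios to WT that rule would choose probe sets by how much they rose, so the mean of a gene's probe sets, listed beforehand as another way, became the reported rule. Among called genes with several probe sets, 136 in number, 1 had probe sets that differed in sign. The planned rule was run as an alternative.

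STAT5b-deficient and WT arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over the 6 arrays of these groups only, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. REF was compared with WT in the same way, as 1 sample against 3. Values are given as ratios to WT (mean ± SD over 3 arrays) or log2 fold changes ± the standard error of the fit. Folds come from the means of log2 ratios, not from the means of ratios. A fold against a group with an array at the floor is a lower bound and is written as "at least".

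Lists of genes for pathways, cell types and gut position, 36 in all, were fixed before the data were examined. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 36 lists. Each was tested again with an estimated correlation, and with fry. Camera sets the members of a list against all other genes.

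Genes were named by a rule set before the data were examined. It takes Stat5b and Stat5a, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, and for each list described up to 4 members with the smallest p. It adds Pparg, Nfkbia, Tnf, Igf1, Socs2, Cish, Cldn2, Ocln and Tjp1, and the 3 genes with the smallest p in each direction for REF. Xist and Y-linked genes, left out of the rises and falls, served as a check of the sex labels. Predicted and unnamed genes counted in totals only. Socs2 was not analysed here, as no probe set matched it. Of the genes this rule takes, 2 are not reported here.

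The scripts were tested on simulated data made from the spread of the real arrays, over 14351 genes. For STAT5b-deficient against WT the test recovered 0% of genes changed by 0.5, 52.8% of genes changed by 1 and 91.9% of genes changed by 2 on the log2 scale, and called 4 unchanged genes. For REF against WT it recovered 0% at each of these sizes. The changed genes numbered 66, 72 and 62 by size in the first comparison and 68, 77 and 55 in the second. Noise was independent between genes. Far fewer genes were changed than were called in the real data, and the adjustment depends on that number. These rates therefore do not carry over to the real comparisons.

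Alternatives tried were other choices of the wild type arrays, the replicate number as a block, every probe set by itself, robust variance, array weights, median centring, quantile normalization, a test against a 1.2-fold change and leaving out each array in turn. Added as alternatives after seeing the data were the highest-mean probe set rule, first planned as the main rule, a floor of 0.05 and REF in place of WT replicate 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.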

Results

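The series profiles gene expression in the colon of adult wild type mice and of mice deficient in STAT5b, a transcription factor activated by growth hormone, prolactin and several cytokines. It holds 3 WT arrays, 3 arrays labelled STAT5b-/- and the REF sample, deposited as 2 columns that differed by less than the sampling noise and were counted as 1 sample. Each value is a ratio to the mean of the 3 WT arrays. Array medians over the 26180 probe sets lay between 0.948 in REF and 1.04 in WT replicate 2. The SD of the log2 ratios within an array was 0.289 to 0.363 in the WT arrays, 0.402 in REF and 0.646 to 0.737 in the arrays labelled STAT5b-deficient. WT arrays are held together by the division by their own mean, so these SDs are not directly comparable. The labels give 1 male, STAT5b-deficient replicate 1, and females otherwise.

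The targeted gene was examined first, as a check of the labels. Stat5b has 1 probe set, NM_011489_at, with ratios of 1.08, 0.930 and 0.993 in the WT arrays, 1.16, 1.17 and 1.26 in the arrays labelled STAT5b-deficient, and 1.18 in REF. Its log2 fold change was 0.26 ± 0.12 (SE) and did not pass the limma test (adjusted p = 0.175). Stat5a, its close relative, had a log2 fold change of -0.24 ± 0.15 (adjusted p = 0.306). Stat5b was thus not measured lower in the arrays labelled STAT5b-deficient. The labels do not say which part of the gene the mutation removes, and a probe set outside that part checks nothing, so every direction given here rests on the labels.

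The main comparison asks which genes differ between wild type and STAT5b-deficient colon. In the arrays labelled STAT5b-deficient, genes of xenobiotic metabolism, fatty acid oxidation and absorptive colonocytes were higher, and genes of goblet cells, the unfolded protein response, the matrix and several immune cell types were lower by camera with its preset correlation, while 0 of the 36 lists passed with an estimated one. S100g, a calcium-binding protein of absorptive epithelium, was 159-fold higher, with a mean ratio of 159 ± 35.0 (SD, n = 3). Insl5, a peptide hormone of colonic enteroendocrine cells, was at least 97.4-fold lower, with 2 of its 3 values at the floor. Of 14351 genes, 1910 were higher and 1209 lower (limma, adjusted p under 0.05), which is 21.7% of genes. The groups were fully apart in all 3119 called genes and in 41.5% of all genes, where chance gives 10%. At least 2-fold changes were seen in 721 genes called higher and 514 called lower, and at least 8-fold changes in 44 and 53. The median log2 fold change over all genes was 0.007. Calls numbered 1180 higher and 734 lower without STAT5b-deficient replicate 1, 1053 and 663 without replicate 2, 1118 and 734 without replicate 3, and 2192 and 1359 without WT replicate 2. Quantile normalization left 158 higher and 239 lower, so that 39.8% of calls were higher against 61.2% in the reported fit.

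The largest rises included transporters and enzymes of the gut epithelium. Slc51a, a subunit of the basolateral bile acid exporter, rose 61.4-fold, Ces1g, a carboxylesterase, 54.9-fold, and Slc30a10, a manganese exporter, 48.5-fold. The sugar phosphate exchanger Slc37a2 rose 42.4-fold and Mal, a protein of apical membrane traffic, 36.8-fold. Prap1 rose 31.8-fold, the arginase Arg2 29.3-fold, Epop 27.9-fold, the peptide hormone neurotensin (Nts) 25.8-fold and the acute-phase protein Saa3 21.5-fold. The SE of the log2 fold change was from 0.14 for Slc30a10 to 0.84 for Mal, and adjusted p from 1.1e-05 for Slc30a10 to 0.00653 for Mal. REF had ratios of 0.397 for Mal to 2.65 for S100g. The WT arrays themselves differed in Mal, with ratios of 0.404, 0.198 and 2.40, and in Slc37a2, with 0.999, 1.65 and 0.355, so these folds depend on which WT arrays are used.

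**Figure D1:**
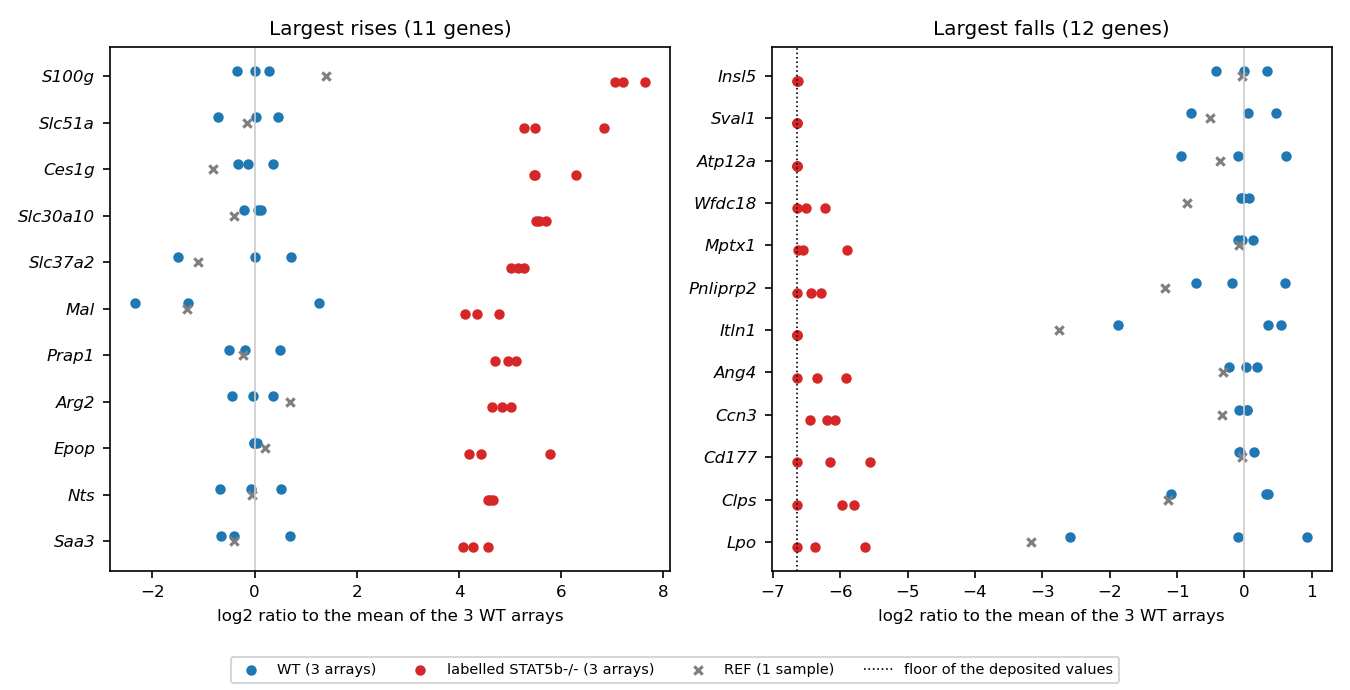
Log2 ratio to the mean of the 3 WT arrays in each array for 11 of the 12 genes with the largest rise (left) and the 12 with the largest fall (right); blue points are WT, red points the arrays labelled STAT5b-deficient, grey crosses REF, and the dotted line is the floor at a ratio of 0.01. All 23 genes separate the WT from the STAT5b-deficient arrays, as the rule that picked them requires. Sval1, Atp12a and Itln1 lie at the floor in all 3 STAT5b-deficient arrays.

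Among the falls, Sval1, the proton pump subunit Atp12a and the lectin Itln1 were at the floor in all 3 arrays labelled STAT5b-deficient. They were at least 93.9-fold, 91.0-fold and 79.6-fold lower. Wfdc18, the pancreatic lipase relative Pnliprp2 and the angiogenin Ang4, an antimicrobial ribonuclease, were at least 88.0-fold, 81.9-fold and 78.5-fold lower. Mptx1, a pentraxin, fell 82.0-fold, and the matricellular protein Ccn3 fell 75.8-fold. Cd177, colipase (Clps) and lactoperoxidase (Lpo) were at least 69.3-fold, 64.0-fold and 49.7-fold lower. In REF the ratios of these genes lay between 0.111 for Lpo and 0.974 for Cd177, and that of Itln1 was 0.148. The WT arrays themselves differed in Itln1, with ratios of 1.46, 0.273 and 1.27, and Lpo had an SD of 0.866 around its WT mean. Adjusted p for the falls was at most 0.00482, for Lpo.

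Of the 36 gene lists, 7 were higher and 11 lower by camera with its preset correlation. With an estimated correlation 0 passed (6 had an unadjusted p under 0.05), and fry called 16, of which 14 were among these 18. Fry did not call mast cell markers (adjusted p = 0.0511), GH and IGF axis genes (0.0694), NF-kB target genes (0.0694) and pancreas and lymphoid contaminants (0.0857), and called enteroendocrine (0.0391) and adipocyte markers (0.0323) instead. None of the medians of the 18 lists past the camera threshold changed sign under quantile normalization. Median centring moves all list medians by the same amount, too small to change any of these signs, so it could not test them.

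Xenobiotic metabolism genes, which oxidise, conjugate or export foreign compounds, were higher: 24 of 34 rose and 0 fell, 25 and 1 adjusted over the list alone (camera adjusted p = 6.41e-11; adjusted p = 0.144 with an estimated correlation). Beside Ces1g they included Ces2e with a log2 fold change of 3.09 ± 0.15, Cyp2d26 with 2.35 ± 0.18 and Cyp2j6 with 1.72 ± 0.13. PPAR target and fatty acid oxidation genes were also higher, with 21 of 27 risen and 1 fallen, 21 and 2 adjusted over the list alone (camera adjusted p = 9.39e-09; adjusted p = 0.144 with an estimated correlation). Ehhadh of peroxisomal oxidation rose by 1.61 ± 0.15, the acylcarnitine carrier Slc25a20 by 1.45 ± 0.16 and Cpt2 by 1.44 ± 0.13. Pparg itself, a nuclear receptor of lipid metabolism, rose by 2.05 ± 0.28 (limma adjusted p = 0.00372). Oxidative phosphorylation genes were higher with 13 of 31 risen and 0 fallen, 13 and 0 adjusted over the list alone (camera adjusted p = 1.83e-06; adjusted p = 0.236 with an estimated correlation). Their rises were small, for example 0.82 ± 0.12 for Uqcrfs1 and 0.80 ± 0.12 for Sdhb, and the list median of 0.40 compares with 0.20 for REF over WT.

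Absorptive colonocyte markers were higher, with 16 of 25 risen and 3 fallen, the same counts adjusted over the list alone (camera adjusted p = 4.18e-05; adjusted p = 0.144 with an estimated correlation). Tmigd1 rose by 2.79 ± 0.27, the water channel Aqp8 by 1.45 ± 0.15 and the butyrate transporter Slc16a1 by 1.34 ± 0.14 on the log2 scale. Tight and adherens junction genes, which seal neighbouring epithelial cells, rose in 10 of 26 and fell in 2, 12 and 2 adjusted over the list alone (camera adjusted p = 0.0286; adjusted p = 0.236 with an estimated correlation; adjusted p = 0.0506 without WT replicate 2). Cldn4 rose by 4.40 ± 0.39, Cldn23 by 1.16 ± 0.17 and Ocln by 0.70 ± 0.13, while Cldn8 fell by 1.97 ± 0.18. Cldn2 and Tjp1 had log2 fold changes of -0.14 ± 0.19 and 0.27 ± 0.13 and did not pass (limma adjusted p = 0.649 and 0.190).

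Genes used in the anterior part of the gut axis, mainly Hox genes of low group number, rose in 7 of 14 and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.236 with an estimated correlation). Hoxb6 rose by 3.94 ± 0.29, Hoxb8 by 3.69 ± 0.12, Hoxb4 by 1.59 ± 0.12 and Hoxd4 by 1.01 ± 0.14. The list of posterior position genes did not pass (3 of 12 higher, 2 lower, camera adjusted p = 0.552). Its members went both ways, as Hoxd9 rose by 3.12 ± 0.24 and Hoxd10 by 2.45 ± 0.39 while Hoxb13 fell by 4.89 ± 0.58 and Hoxa13 by 1.43 ± 0.30. Circadian clock genes rose in 5 of 18 and fell in 0, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.297 with an estimated correlation). Nr1d1 rose by 1.89 ± 0.21 and Dbp by 1.00 ± 0.26. The clock list's call ended without WT replicate 2 (adjusted p = 0.173) and without STAT5b-deficient replicate 1 (adjusted p = 0.0661).

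**Figure D2:**
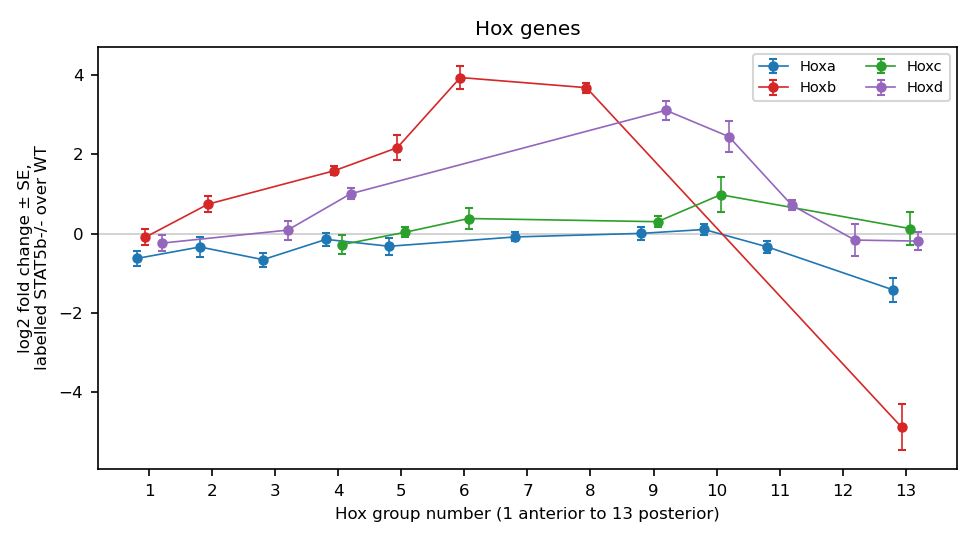
Log2 fold change (arrays labelled STAT5b-deficient over WT, 3 against 3) of 31 Hox genes against their group number, by cluster; error bars are the standard error of the fit. Hoxb4 to Hoxb8 and Hoxd9 to Hoxd11 lie above 0, Hoxb13 lies at -4.89, and most genes of the Hoxa and Hoxc clusters lie near 0.

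Goblet cell markers were lower, with 13 of 16 fallen and 0 risen, 14 and 0 adjusted over the list alone (camera adjusted p = 6.62e-12; adjusted p = 0.115 with an estimated correlation). Goblet cells secrete the mucus layer. Capn9 fell by 3.27 ± 0.15, the transcription factor Spdef by 3.07 ± 0.18, the endoplasmic reticulum sensor Ern2 by 2.30 ± 0.16 and Sytl2 by 2.16 ± 0.12. Unfolded protein response genes fell in 14 of 20 and rose in 0, 15 and 0 adjusted over the list alone (camera adjusted p = 7.21e-09; adjusted p = 0.236 with an estimated correlation). Asns, which makes asparagine, fell by 2.0 ± 0.16, Creld2 by 1.36 ± 0.12, Pdia6, a protein disulfide isomerase, by 1.29 ± 0.13 and Manf by 1.24 ± 0.13. Antimicrobial and epithelial defence genes fell in 8 of 21 and rose in 2, the same counts adjusted over the list alone (camera adjusted p = 0.0351; adjusted p = 0.493 with an estimated correlation). Beside Ang4 and Itln1, Retnlb, a goblet cell product, fell by 3.0 ± 0.27, while Sprr1a, a cornified envelope protein, rose by 2.77 ± 0.17. The median log2 change of this list was -0.32, and -0.40 for REF over WT, so a wild type sample lay as low, with the WT arrays shared by both differences. Tuft cell markers fell in 5 of 15 and rose in 0, 8 and 0 adjusted over the list alone (camera adjusted p = 0.000284; adjusted p = 0.474 with an estimated correlation). Hpgds fell by 1.76 ± 0.20 and Dclk1 by 0.79 ± 0.12.

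Fibroblast and matrix genes were lower, with 15 of 22 fallen and 0 risen, 18 and 0 adjusted over the list alone (camera adjusted p = 3.1e-09; adjusted p = 0.297 with an estimated correlation). The matrix genes Fbln1, Lum, Dcn and Dpt fell by 1.76 ± 0.15, 1.36 ± 0.20, 1.11 ± 0.14 and 1.08 ± 0.15. Macrophage and dendritic cell markers fell in 12 of 23 and rose in 0, 13 and 0 adjusted over the list alone (camera adjusted p = 2.94e-06; adjusted p = 0.474 with an estimated correlation). Adgre1 (F4/80) fell by 1.93 ± 0.29, the mannose receptor Mrc1 by 1.92 ± 0.19 and lysozyme Lyz2 by 1.33 ± 0.19. B and plasma cell markers fell in 7 of 18 and rose in 0, 8 and 0 adjusted over the list alone (camera adjusted p = 1.56e-05; adjusted p = 0.337 with an estimated correlation). The falls were 2.88 ± 0.41 for Pou2af1, 2.65 ± 0.27 for Mzb1 and 2.11 ± 0.23 for Tnfrsf17. Mast cell markers fell in 4 of 11 and rose in 0, 7 and 0 adjusted over the list alone (camera adjusted p = 0.000843; adjusted p = 0.468 with an estimated correlation). Among them the mast cell proteases Mcpt2 and Mcpt1 fell by 4.15 ± 0.85 and 3.81 ± 0.62. In WT replicate 2 the median log2 ratio of the mast cell markers lay 0.86 above the mean of the other WT arrays, and that of the tuft cell markers 0.62 above.

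**Figure D3:**
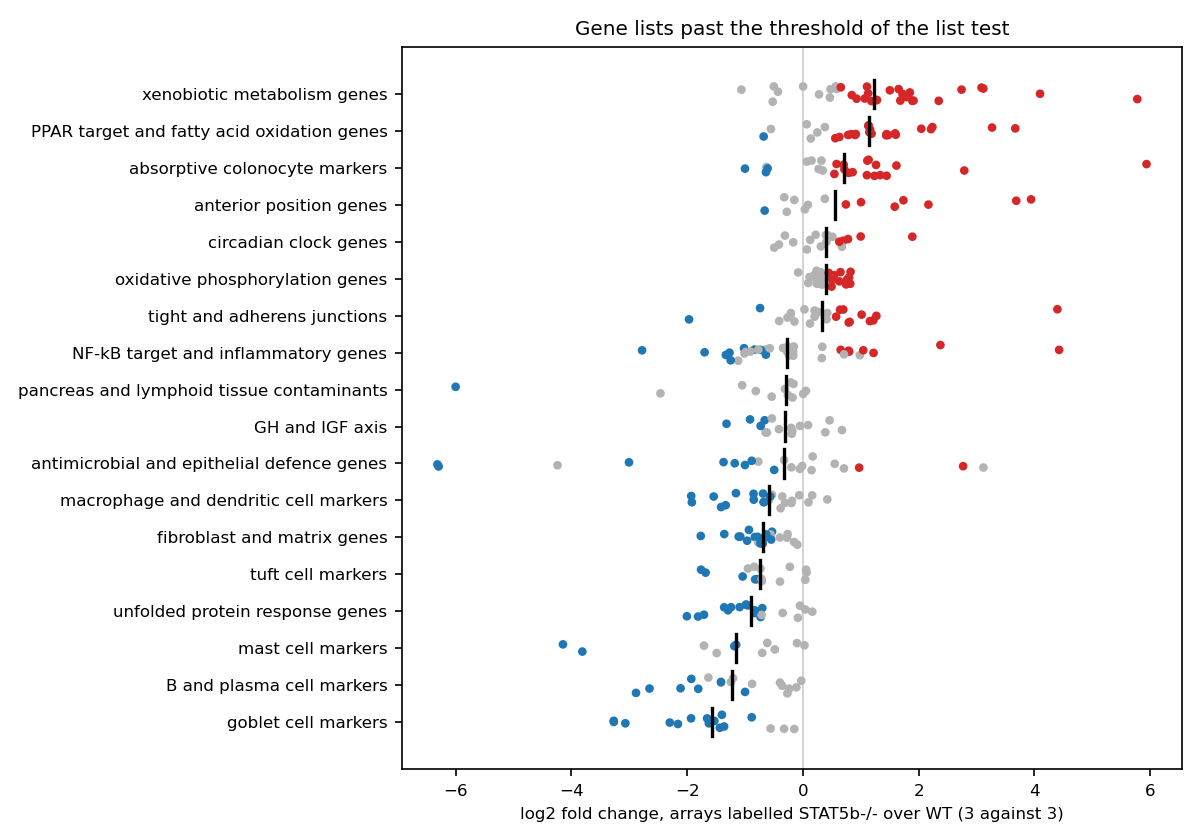
Log2 fold change (arrays labelled STAT5b-deficient over WT) of each measured member of the 18 gene lists past the camera threshold; red points were called higher, blue points lower, grey points did not pass, and black bars are list medians. Medians run from -1.58 for goblet cell markers to 1.23 for xenobiotic metabolism genes.

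A further 3 lists passed as lower near the threshold, and lost the call without WT replicate 2. GH and IGF axis genes, which carry growth hormone signals, fell in 4 of 16 and rose in 0, the same counts adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.535 with an estimated correlation; adjusted p = 0.0818 without WT replicate 2 and 0.052 without STAT5b-deficient replicate 3). The falls were in Igfbp2 (1.32 ± 0.29), Igf2r (0.91 ± 0.16), Igfbp7 (0.73 ± 0.13) and Igfbp4 (0.66 ± 0.16), which bind or clear insulin-like growth factors, while Igf1 had a log2 fold change of -0.41 ± 0.15 that did not pass (limma adjusted p = 0.0896). NF-kB target and inflammatory genes fell in 9 of 35 and rose in 7, 14 and 7 adjusted over the list alone (camera adjusted p = 0.0405; adjusted p = 0.493 with an estimated correlation; adjusted p = 0.0686 without WT replicate 2). Mmp10 fell by 2.78 ± 0.16 and the endotoxin receptor Tlr4 by 1.25 ± 0.14, whereas Saa3, the chemokine Ccl5 (2.38 ± 0.27) and the NF-kB inhibitor Nfkbia (0.80 ± 0.15) rose. Tnf had a log2 fold change of -0.62 ± 0.23 (limma adjusted p = 0.0974). The list of pancreas and lymphoid tissue contaminants had 1 called member, Clps, out of 12 (camera adjusted p = 0.0272; adjusted p = 0.575 with an estimated correlation; adjusted p = 0.145 without WT replicate 2). Its median in WT replicate 2 lay 0.80 above the mean of the other WT arrays. The median log2 changes of these 3 lists were -0.31 for the GH and IGF axis, -0.27 for NF-kB targets and -0.28 for the contaminants. For REF over WT they were -0.16, -0.24 and -0.49, so a wild type sample moved the same way. Both differences share the WT arrays, so the shared sign is not independent.

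STAT5 target genes did not pass as a list: 2 of 18 were higher and 2 lower (camera adjusted p = 0.386). Bcl2l1 rose by 0.96 ± 0.13 and Cdkn1a by 1.31 ± 0.22, while the anti-apoptotic Bcl2 fell by 1.31 ± 0.17 and Socs3, a feedback inhibitor of cytokine signals, fell by 1.22 ± 0.13. Cish, a classical STAT5 target, had a log2 fold change of -0.21 ± 0.14 (limma adjusted p = 0.348). JAK-STAT components had 3 of 23 higher and 2 lower (camera adjusted p = 0.916). Enteroendocrine cell markers had 2 of 17 higher and 6 lower (camera adjusted p = 0.0524). Nts rose, the hormone secretin (Sct) rose by 2.23 ± 0.19, and peptide YY (Pyy) fell by 1.94 ± 0.18, beside the fall of Insl5. T cell markers had 6 of 21 higher and 2 lower (camera adjusted p = 0.221), with Ccl5 and Nkg7 (1.45 ± 0.16) risen and Cd2 and Cd28 fallen by 1.24 ± 0.18 and 1.49 ± 0.25. Small intestine markers had 4 of 16 higher and 2 lower (camera adjusted p = 0.221), as the ileal bile acid transporter Slc10a2 rose by 4.0 ± 0.38 and the peptide transporter Slc15a1 fell by 3.74 ± 0.42. Immediate early and heat shock genes had 7 of 21 higher and 1 lower (camera adjusted p = 0.221), and stem cell and crypt base markers 2 of 16 higher and 4 lower, 4 and 5 adjusted over the list alone (camera adjusted p = 0.296). Some of these lists passed when an array was left out: enteroendocrine markers as lower without WT replicate 1 (adjusted p = 0.0448), STAT5b-deficient replicate 1 (0.0499) or replicate 3 (0.037), immediate early genes as higher without WT replicate 1 (0.0304), and small intestine markers as higher without STAT5b-deficient replicate 2 (0.0271).

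The remaining lists did not pass either. Regulatory T cell markers had 2 of 11 lower, among them Il10, which fell by 1.98 ± 0.24 to a mean ratio of 0.246 but had a ratio of 0.293 in REF, and neutrophil markers had 0 of 12 called (camera adjusted p = 0.137 and 0.107); the latter passed as lower without WT replicate 1 (adjusted p = 0.0462) or replicate 3 (0.0389). Adipocyte markers had 5 of 15 higher, led by the lipid droplet protein Cidec with 3.37 ± 0.32, and a median of -0.03 that went against their mean (camera adjusted p = 0.437). Cell cycle genes had 2 of 28 higher and 2 lower, and cholesterol synthesis genes 2 of 22 higher and 1 lower (camera adjusted p = 0.850 and 0.525). Endothelial markers had 1 of 18 higher and 3 lower, enteric neuron and glia markers 1 of 19 higher and 2 lower, and smooth muscle markers 1 of 17 higher (camera adjusted p = 0.357, 0.445 and 0.934). Antigen presentation and interferon gamma genes had 3 of 26 higher and 1 lower, and type I interferon response genes 1 of 20 higher (camera adjusted p = 0.597 and 0.386); the latter passed as higher without WT replicate 3 (adjusted p = 0.034). Adjusted over the list alone, antigen presentation had 1 higher and 0 lower, and the counts of the other lists that did not pass, apart from stem cell markers, were as over all genes. Median, mean and test differed in sign in 5 lists, namely adipocyte, cholesterol synthesis, cell cycle, JAK-STAT and smooth muscle.

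The comparison of REF with WT sets a wild type sample against the WT arrays and gives a background for the comparison above. The smallest p among higher genes belonged to Tlr1, a receptor for bacterial lipopeptides, with a ratio of 3.30 in REF and 6.15 ± 0.29 (SD, n = 3) in the arrays labelled STAT5b-deficient. Next came Shisa3 with a ratio of 2.27 and the cell cycle gene Cdca3 with 2.21, whose mean ratios in the arrays labelled STAT5b-deficient were 0.465 and 1.14. Among lower genes, Ap1s3 had a ratio of 0.161, Pik3cg 0.332 and the lipid droplet enzyme Hsd17b13 0.0471, and their mean ratios in the arrays labelled STAT5b-deficient were 0.122, 0.223 and 0.0711. Both comparisons share the WT arrays, so changes in the same direction are not independent. By limma no gene passed, and with REF as 1 sample the p-values carry little weight. A log2 difference of at least 1 in either direction was found in 236 genes, against 1348 for the arrays labelled STAT5b-deficient, whose means average 3 arrays. In a simulation that changed few genes, the test recovered 0% of them even at a 4-fold change. That rate does not carry over to the real comparison. With 1 sample against 3 and no spread within REF, a lack of calls cannot show that REF and WT are alike.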

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

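Results were recomputed under alternatives planned before the data were examined, and under 3 added as alternatives after seeing the data. The latter were the highest-mean probe set per gene, which had been the planned main rule, ratios under 0.05 raised to 0.05, and REF in place of WT replicate 2. With REF in place of WT the arrays labelled STAT5b-deficient had 800 genes higher and 495 lower, with 1 sample setting the wild type level, and 40 of the 3119 called genes changed direction. There Cish (0.076), Elavl4 (0.10), Mpo (0.18) and Ifi44 (0.10) took the opposite sign on the log2 scale; none was called in the reported fit, and the cause was not tested. Every probe set by itself gave 2911 higher and 2188 lower, as unnamed probe sets entered, and the test against a 1.2-fold change gave 1027 and 643. Quantile normalization gave 158 and 239 and kept 397 of the calls; it forces one distribution on all arrays, while WT ratios are narrower by construction. Leaving out each array in turn gave 1053 to 2192 genes higher and 663 to 1359 lower. No called gene changed direction, which was fixed in advance, since the groups do not overlap in any of the 3119 called genes. The replicate block gave 1238 higher and 801 lower, with 1978 of 3119 calls shared, but arrays of equal number did not deviate together (correlations 0.036, -0.098 and -0.186), so the numbers do not pair the samples; no array labelled STAT5b-deficient correlated best with the WT array of its own number. The other gene counts lay within 1.5 times those reported, from 1846 to 2806 higher and from 1125 to 1758 lower, and fitting the 3 groups together moved nothing. The 7 lists higher and 11 lower became 0 and 0 with an estimated correlation, 5 to 8 and 8 to 13 on leaving out an array, and 6 to 8 and 8 to 12 otherwise. Of 167 named genes besides Stat5b, 84 kept their side of the threshold under quantile normalization, 127 with REF in place of WT and 149 to 163 on leaving out an array. The 24 largest changes kept their call except for 5 under quantile normalization. Stat5b stayed above 0 and short of the threshold throughout, from 0.02 with REF in place of WT to 0.32 without WT replicate 1 (adjusted p from 0.0899 to 0.943). REF against WT gave 0 genes in every setting run. Not run were the filters on dim probe sets, the intensity trend and the percentile floor, since ratios hold no level, and, for REF, which is 1 sample, the replicate block and leaving REF out. Signal over background is unknown here, so genes near the floor have no order.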

Other observations

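The gene families below, 23 in all, and every test in this part except those on a mutant transcript, on the receptor genes and on other groupings of the arrays were chosen after the results were seen. Counts are over called genes, with two-sided Fisher's exact tests against all genes tested, adjusted over 46 tests. The test treats genes as independent, which members of a family need not be, and the families were picked from these same results. Its p-values are therefore not error rates, and no test that allows for correlation was run on the families. No family median changed sign under quantile normalization. Median centring moves all family medians by the same amount, too small to change any of these signs. UDP-glucuronosyltransferases, which conjugate bilirubin, hormones and drugs, were higher in 11 of 17 in the arrays labelled STAT5b-deficient (adjusted p = 5.94e-05), but Ugt1a members share exons and cannot be counted as independent. Carboxylesterases were higher in 7 of 11 and lower in 1 (adjusted p = 0.0017), with Ces2b at 3.33 ± 0.16 and Ces2a at 3.0 ± 0.25 on the log2 scale. Mitochondrial ribosomal proteins were higher in 20 of 73 and lower in 0 (adjusted p = 0.0124), while cytosolic ribosomal proteins were higher in 1 of 25 (adjusted p = 0.473). Acyl-CoA thioesterases were higher in 6 of 12 (adjusted p = 0.0124).

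Sialyltransferases, which cap mucin and other glycans, were lower in 8 of 19 and higher in 2 (adjusted p = 0.00123). St3gal6 fell by 5.32 ± 0.16 and St3gal3 by 2.61 ± 0.22, while St3gal5, which makes the ganglioside GM3, rose by 3.76 ± 0.16. Fucosyltransferases were lower in 4 of 8, among them Fut8 (-1.70 ± 0.20) and Fut2 (-0.97 ± 0.14) (adjusted p = 0.0124). Genes of the secretory pathway's vesicle coats and signal recognition were lower in 10 of 26 (adjusted p = 0.000604), with Sec24d at -1.05 ± 0.13 and Sec23a, at 0.76 ± 0.16, the other way. Chemokines were lower in 8 of 30 (adjusted p = 0.0124), led by Ccl8 (-3.38 ± 0.31) and Ccl6 (-2.96 ± 0.14), and higher in 2, Ccl5 (2.38 ± 0.27) and Ccl25 (1.39 ± 0.18); 12 of the 30 also stand in the fixed lists. No enrichment was found at an adjusted p under 0.05 for ABC transporters, aldehyde dehydrogenases, B3gnt and Galnt enzymes, claudins, aquaporins, proteasome subunits, keratins, zinc transporters and bile acid transporters. The same held for genes with symbols starting with Cyp2 or Cyp4, taken by name, so that Cyp20a1 of another family entered. Of 35 Cyp2 symbols 5 were higher and 5 lower, the latter including Cyp2d34 (-2.43 ± 0.32) and Cyp2d9 (-2.39 ± 0.34). Protein disulfide isomerases (3 of 4 lower, adjusted p = 0.0124) overlap the unfolded protein response list, and olfactory receptors had 0 of 38 called, fewer higher than among all genes (adjusted p = 0.0302).

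In all, 21.7% of genes differed between the arrays labelled STAT5b-deficient and WT. Other groupings of the 6 arrays are too few for a share under 0.05: the real grouping, with 3119 genes, was 1 of 10, and the highest of the others had 0. Another share of muscle wall goes against a smooth muscle median of -0.011 (SE 0.07, and 0.016 under median centring) beside a median change of 0.87 over called genes. This SE resamples the 17 markers as if independent, although their estimated correlation was 0.56, and holds no spread between arrays. In WT replicate 2 the median of these markers lay 0.32 below the mean of the other WT arrays, so the SE is too small. Small intestine RNA stays open: its 16 markers went both ways, and their median of 0.51 (SD 1.58) lay below 0.87 by less than that SD. Of the 40 measured genes nearest to Stat5b, 10% ± 4.7 were called against 21.7% of all, where the ± treats neighbouring genes as independent. Genes next to Stat5b were thus not called more often than others. With 40 of them against 3119 calls, their share could not show what the main source is. Strain DNA that acts on genes elsewhere, or lies elsewhere in the genome, was not tested and stays open. A different stretch of colon in the samples may contribute and stays open: the order of all 31 Hox genes gave no relation (Spearman's rho across genes 0.051, permutation p = 0.786, 95% bootstrap interval -0.35 to 0.45). A contrast chosen only after that test and after Hoxb13 was seen set the 4 group 13 genes (mean -1.60) against the other 27 (mean 0.67, exact permutation p = 0.00779). It depends on Hoxb13, without which the exact permutation p was 0.113, with only 3 group 13 genes left. Of these, Hoxa13 was also called lower (-1.43 ± 0.30, limma adjusted p = 0.0163), while Hoxc13 (0.13 ± 0.41) and Hoxd13 (-0.19 ± 0.22) were not called. An effect of the STAT5b genotype also stays open.

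Stat5b was not lower in the arrays labelled STAT5b-deficient. Exchanged labels, in a mutant that loses the transcript, would need Stat5b lower by at least 1 in the WT arrays, and the log2 difference was 0.26 ± 0.12. A mutant transcript that the probe set still reads may explain the value; this cannot be told apart from other accounts, since the number of Stat5b probe sets is 1. A mutation that leaves the transcript level intact was not tested.

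WT replicate 2 stood apart from the other wild type arrays. It had 98 genes more than 4-fold above the mean of the other WT arrays, against 6 for WT replicate 1 and 12 for WT replicate 3, and its limma array weight was 0.218, the lowest of the 6. Over 39 olfactory and trace amine receptor genes, most of which colon is not known to use, its median log2 excess was 0.78 ± 0.10 (SE) with 37 of 39 above 0, against 0.08 over all genes. A raised signal of silent genes, as from a weaker hybridization, is a candidate explanation of this excess in the receptor genes. It was not tested for larger differences of single genes, such as that in Pla2g2a, and no biological explanation was tested. Pla2g2a, a phospholipase absent from some mouse strains, had a ratio of 2.90 in WT replicate 2 and 0.048 in WT replicates 1 and 3. It had 0.045 in REF and lay at the floor in all arrays labelled STAT5b-deficient. Nxpe4 was high in WT replicate 2 and REF, with ratios of 2.75 and 1.51, against 0.108 and 0.144 in WT replicates 1 and 3. Its mean ratio in the arrays labelled STAT5b-deficient was 0.093. For Nxpe4, WT replicate 2 thus did not stand alone among the wild type samples. Both genes were picked after their values were seen.

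The sex labels had no counterpart in the values: in the array labelled male the 4 Y-linked genes had ratios of 0.824 to 1.00 against 0.811 to 1.24 in the arrays labelled female, and the 2 Xist probe sets 0.914 and 0.985 against 0.751 to 1.12.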
